A study of Mus musculus with 4 samples.

How the data were processed

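Gene expression was measured in CD8α+ and CD8α− dendritic cells of C57BL/6 mouse spleen, with 2 arrays per group, grouped by the cell type and title in the labels. The arrays were Affymetrix Mouse Genome 430 2.0 arrays, per the series' design text. The sources describe the RNA work in different ways. The series' design text names RNeasy extraction, Oligotex mRNA purification and biotin-labelled cDNA made from 100 ng of mRNA with the Ovation Biotin System. The labels' protocols name Trizol extraction and biotinylated cRNA made from 6 µg of total RNA, and which was used is not settled here. How the cells were isolated or sorted is not given in the sources used here.

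The authors deposited intensity values on a linear scale, 1 MAS5 signal per probe set and array. MAS5 is named in the submitters' processing notes, and Microarray Suite 5.0 and GeneSpring are named in the series' design text. The scaling target is not given in the sources used here. The table carries no detection calls. The values of the arrays were not on a common scale: the deposited signals had a mean, after trimming 2% at each end, of 124, 127, 106 and 48.7 on CD8α+ replicates 1 and 2 and CD8α− replicates 1 and 2. The hybridization spike controls (18 probe sets) had medians of 1636, 2299, 1795 and 1371 on the same arrays, and the Bacillus control probe sets (27) had medians of 6.20, 3.20, 9.00 and 4.30. The plan had taken the deposited values as already scaled between arrays. Since they were not, the arrays were quantile normalized, which the plan held as an alternative. The deposited scale became the alternative, a change made from the distributions of the arrays and not from any comparison of the groups.

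Probe sets were named through the platform annotation. Of 45101 probe sets, 64 were controls and left out. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none. Probe sets with several symbols were not named. For 34741 of those with 1 symbol the Entrez identifier was found in the RefSeq gene table, and 0 symbols were updated. After normalization, signals were raised to a floor of 6.99, the mean over the arrays of the 25th percentile, and log2 transformed. Probe sets were tested when their mean linear signal was at or above the median, 23.0, which left 22519 probe sets and 10531 genes. A gene was represented by its tested probe set with the highest mean signal, leaving out names ending in _x_at where the gene had another. Background was taken as the highest Bacillus control of each array, 33.6, 20.1, 39.6 and 23.6 in the order above, which became 30.8, 21.8, 28.3 and 34.5 after normalization. Where no array of a group exceeded it, the fold is given as "at least", the brighter group's mean over that of the higher of background and own signal on each array. No fold is given where 1 array of a group did not exceed it. Among named genes this held in CD8α+ cells for Cd4, Cebpb, Dscam, Ifit1, Ifit3, Il2rb, Il10, Klra8, Ncr1 and Oas2, in CD8α− cells for Fgd6, Il15, Itgae, Sema4a and Tapbpl, and in both for Siglech. Fitted differences of such genes rest on signals within background and their size is not exact.

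The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, two-sided, with Benjamini-Hochberg adjustment at 0.05). The fit had 2 residual and 2.48 prior degrees of freedom. No exact permutation test of 2 arrays against 2 was used, since it cannot give a two-sided p below 0.333. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists. With the estimated correlation 0 lists passed after adjustment, against 12 with the preset one, and fry gave 17. For some of the 12 the estimate was below the preset value, as for conventional type 2 dendritic cell (cDC2) markers (-0.00646). Their unadjusted camera p still went from 5.52e-10 to 0.0213, so a higher correlation does not account for that loss. For type 1 (cDC1) markers the estimate was higher, 0.0639. With an estimated correlation camera refers its statistic to the residual degrees of freedom, 2 here. At the preset correlation it uses a far larger number, set by the genes. The camera p-values of these settings therefore differ by more than the correlation. A fry p tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Beyond the 12, fry passed pathogen sensors (adjusted p = 0.0160), MHC class II (0.0308), oxidase (0.0338), B cell (0.0114) and erythroid (0.00389) lists, each lower in CD8α+ cells. Members were also counted when adjusted over the list alone. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

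The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Cd8a on every probe set. It takes the genes with the largest folds past the threshold and, since none passed, the 5 genes with the smallest p in each direction. It takes up to 4 called members of each list in each direction, and members discussed as not called. Other genes are marked as named after their values were seen. List members without a probe set of a single symbol, or below the signal filter, were not analysed here. The retinoic acid-inducible sensor of the plan was matched under the symbol Ddx58.

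The fit was tested on simulated data with the real means of 22519 probe sets, in 10 runs. Spreads were drawn from the fit's prior, alike in both groups, and probe sets varied independently. The real SD between replicates was 0.414 in CD8α+ and 0.817 in CD8α− cells. The simulation therefore does not check the fit under such unequal spreads. With 200 changed probe sets, 0 were called at a change of 1, 2, 3 or 5 log2 units, while 43.0%, 85.6%, 94.6% and 97.8% of them had an unadjusted p under 0.05, against 5.04% of unchanged ones, of which 1 of 223190 was called. With 3000 changed probe sets, 2.03%, 33.2%, 73.9% and 92.3% were called in that order, against 0.368% of unchanged ones. Simulated lists of 20 genes shifted by 2 log2 units had an unadjusted p under 0.05 in 10 of 10 runs by camera with either correlation and by fry. A mean of 16.9 of their members was called over the list alone. The real lists were judged on adjusted p instead. Without adjustment, camera with the estimated correlation gave cDC1 markers p = 0.0325, cDC2 markers 0.0213, Fc and complement receptors 0.0335 and interferon-stimulated genes 0.0390. No other list was under 0.05. The number of arrays limits the precision of every value.

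Alternatives covered the scaling, the floor, the filter, the spread model, a block on the replicate number, each array left out in turn, the fold threshold and the averaging of probe sets. Scaling to a common trimmed mean and array weights were added after seeing the data, when the deposited scale, the plan's main one, also became an alternative. Probe set pairs were the brightest 2 of a gene in the brighter 50% of tested probe sets.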

Results

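Dendritic cells of the mouse spleen fall into a CD8α+ and a CD8α− population. The CD8α+ cells belong to the conventional type 1 lineage (cDC1), known for taking up dying cells and presenting their antigens to CD8 T cells. The CD8α− cells are mostly conventional type 2 cells (cDC2), known for presenting antigen to CD4 T cells. RNA of each population from C57BL/6 mice was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 2 arrays per population and 4 in all. The comparison asks which genes differ in expression between the populations. The labels do not say that the arrays of a group came from separate animals. The limma p-values therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare list members with other genes, so genes are their units. Permutation p-values and bootstrap intervals shuffle or resample genes or probe sets and do not measure the spread between arrays. Differences are given as log2 signal in CD8α+ cells minus CD8α− cells, ± the standard error of the fit, with n = 2 arrays per group.

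The CD8α+ arrays resembled each other more closely than the CD8α− arrays did. Across tested probe sets the log2 signals of the CD8α+ pair correlated at r = 0.955, and 8.47% of probe sets differed over 2-fold. The CD8α− pair correlated at r = 0.835, with 32.2% over 2-fold. Pairs across the populations gave r from 0.788 to 0.871. CD8α− replicate 1 was closer to CD8α+ replicates 1 and 2 (r = 0.861 and 0.871) than to CD8α− replicate 2, so the CD8α− arrays did not group together. These correlations run across probe sets, which are not independent replicates. CD8α− replicate 2 was the dimmest array, with a median deposited signal of 17.4 against 26.6 and 22.9 in the CD8α+ arrays and 35.1 in CD8α− replicate 1. The Gapdh control probe sets read 10.7 times more signal at the 3′ end than at the 5′ end on CD8α− replicate 2, and 1.53, 1.56 and 2.02 times more on the other arrays. The matching Actb ratio was 0.759 on that array and 1.69, 1.62 and 1.67 on the others. In 2326 genes read by a pair of probe sets, the differences between CD8α+ replicate 1 and CD8α− replicate 1 correlated at r = 0.686 across genes between both probe sets. For CD8α+ replicate 2 against CD8α− replicate 2 the value was 0.262, and for the difference between the CD8α− arrays it was 0.0216.

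**Figure D1:**
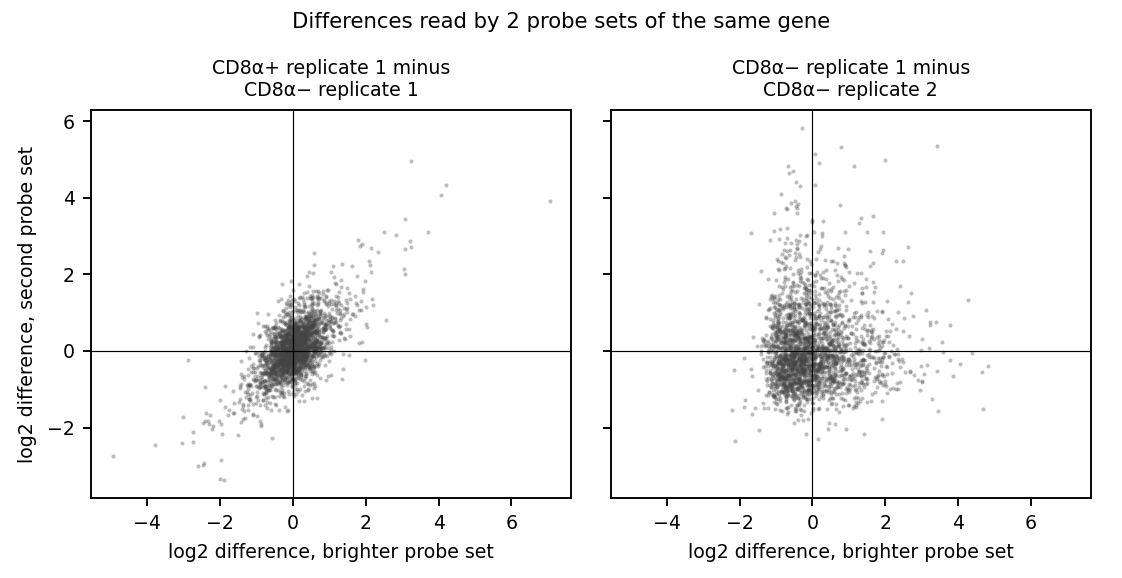
Each point is a gene read by 2 probe sets, with the log2 difference of the brighter probe set on the x axis and that of the second on the y axis, for CD8α+ replicate 1 minus CD8α− replicate 1 (left) and CD8α− replicate 1 minus CD8α− replicate 2 (right). The points follow a diagonal on the left (r = 0.686) and show no slope on the right (r = 0.0216).

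Cd8a, the gene of the antigen that defines the groups, was at least 69.4-fold brighter in CD8α+ cells on its brightest probe set, with a fitted difference of 6.74 ± 0.42. Its deposited signals there were 2640 and 3102 in the CD8α+ arrays against 22 and 19 in the CD8α− arrays, where the highest Bacillus controls read 39.6 and 23.6. The other 4 Cd8a probe sets gave fitted differences of 4.69 (at least 16.7-fold), 3.90, 3.14 (at least 3.65-fold) and 2.82, and on each of the 5 both CD8α+ arrays exceeded both CD8α− arrays, as the labels state. Beyond Cd8a, the genes with the smallest p that were brighter in CD8α+ cells were Mab21l3 (5.12 ± 0.30, at least 7.78-fold), Gm36723 (4.99 ± 0.31, at least 7.13-fold), Fam149a (4.70 ± 0.31, at least 5.79-fold) and Gpr33 (4.57 ± 0.30, at least 5.32-fold). Gpr33 encodes an orphan chemoattractant-like receptor. Each of these 4 was at the floor in both CD8α− arrays. The floor set their spread there to 0, so their standard errors and ranks by p leave out the variation between those arrays. In the other direction stood Mmp12, a macrophage elastase (-4.44 ± 0.38), Abcb1a, a drug efflux pump (-3.64 ± 0.34), and the adhesion molecule Dscam (-3.43 ± 0.31). The junctional adhesion molecule F11r (-3.34 ± 0.30, at least 2.73-fold) and Snap91 (-3.28 ± 0.30, at least 2.62-fold) were at the floor in both CD8α+ arrays, which set their spread there to 0 as well.

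None of these genes passed the threshold over all genes. With limma, 0 of 22519 probe sets and 0 of 10531 genes had an adjusted p under 0.05, the lowest being 0.116. At an unadjusted p under 0.05 there were 3501 probe sets, 1745 brighter and 1756 dimmer in CD8α+ cells, against 1125.95 expected by chance. Of the genes, 738 were brighter and 920 dimmer at that level. Both arrays of a group lay on the same side of both arrays of the other group for 53.7% of genes. Chance gives 33.3% only if all arrays vary alike. The wider spread of the CD8α− pair raises that share, so the size of the excess is not known. Modelling the spread with an intensity trend called 37 genes, 21 brighter and 16 dimmer, Cd8a among them, and centring each array on its median called 195, of which 173 were brighter. Leaving out 1 array leaves a group of 1, which is then assumed to vary like the other group. Without CD8α− replicate 1 the spread is that of the close CD8α+ pair, and only the dimmest array stands for CD8α− cells. Higher counts without it, here and below, therefore do not show differences that it had hidden. At unadjusted p the probe sets numbered 1121 without CD8α+ replicate 1, 1338 without CD8α+ replicate 2, 9728 without CD8α− replicate 1 and 6369 without CD8α− replicate 2. On the scale as deposited, without matching the arrays, the median gene was 0.66 log2 units higher in CD8α+ cells, and the unadjusted calls split into 2310 brighter and 454 dimmer. Scaling to a common trimmed mean moved the median gene to -0.18 and the split to 1280 and 3784, and median centring gave 0.67 and 6018 and 855. Directions of gene groups are therefore given with the arrays matched by quantile normalization, where the median gene stood at -0.02, and were compared with these scalings relative to their shift.

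Gene groups fixed beforehand were tested in 26 lists, and 112 list memberships of 100 genes passed an adjusted p of 0.05 when adjusted over the list alone. None of the members passed over all genes. In each of the 112, both arrays of a group stood apart from both of the other. This adds no support, since the 112 were picked by p on the same arrays, and 53.7% of all genes stood apart too.

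Markers of the cDC1 lineage rose together in CD8α+ cells. Of 23 measured members, 17 were higher, 0 lower and 6 not called when adjusted over the list alone, with a median difference of 1.97. After Cd8a the smallest p belonged to the chemokine receptor Xcr1 (3.13 ± 0.31, at least 6.64-fold), the adhesion molecule Cadm1 (3.72 ± 0.38, 13.2-fold) and the lysosomal thioesterase Ppt1 (3.19 ± 0.34). Irf8, a transcription factor needed for cDC1 development (1.61 ± 0.35), the integrin Itgae (CD103, 3.19 ± 0.82) and the uptake receptor Ly75 (DEC-205, 1.97 ± 0.63) were also among the 17 and are named after their values were seen. The transcription factors Batf3 (-0.27 ± 0.32, adjusted p = 0.476 over the list) and Id2 (0.48 ± 0.31) were not called. Another list also holds 11 of the 23 members. By camera the list stood above the other genes with an adjusted p of 9.03e-13, and with adjusted p = 0.219 with an estimated correlation. The members called numbered 5 without CD8α+ replicate 1 and 8 without CD8α+ replicate 2, where the spread rests on the CD8α− pair, and 8 with no filter on dim probe sets.

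Markers of the cDC2 lineage fell in CD8α+ cells. Of 19 measured members, 12 were lower, 0 higher and 7 not called when adjusted over the list alone, and the median difference was -2.02. The growth factor receptor Csf1r (-2.88 ± 0.35, 7.35-fold), the C-type lectin Cd209a (-2.63 ± 0.33), the T cell co-receptor Cd4 (-3.10 ± 0.49) and the calcium-binding protein S100a4 (-2.27 ± 0.39) had the smallest p. The transcription factor Irf4 (-1.45 ± 0.37), named after its value was seen, fell as well. Zeb2 counted among the 12 through the probe set that represents it (-2.02 ± 0.47), but another of its 5 probe sets read 0.82. Sirpa (-1.81 ± 0.84), Notch2 (-0.64 ± 0.34) and Klf4 (0.08 ± 0.58) were not called. Camera gave an adjusted p of 7.17e-09, and adjusted p = 0.219 with an estimated correlation. On the deposited scale 0 members were called, although the median stayed at -1.50, and without CD8α+ replicate 1 or 2 the count was 1 or 2. Of the 19 members, 15 also stand in another list, so the lists partly count the same genes. Csf1r belongs to the monocyte list too, and called members of the monocyte, macrophage and natural killer (NK) cell lists fell as well, apart from Vcam1.

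**Figure D2:**
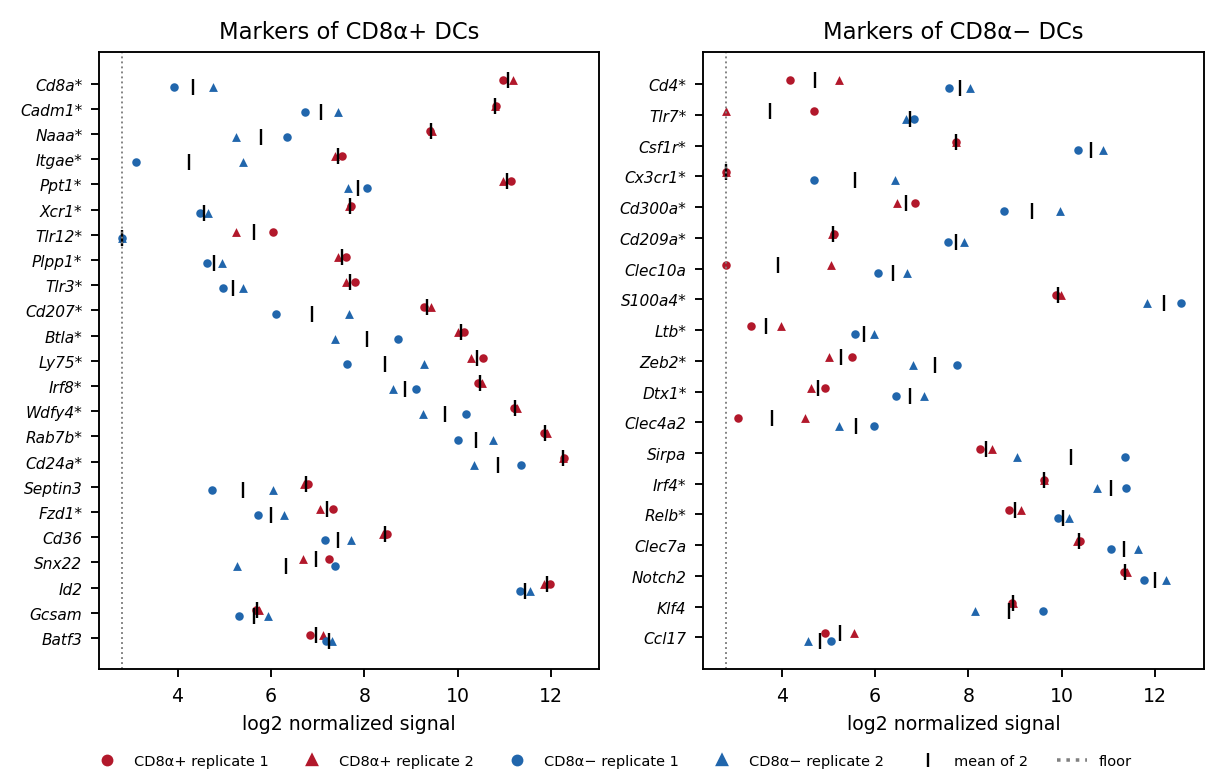
The x axis gives the log2 normalized signal of each list member (rows) on every array, with red for CD8α+ and blue for CD8α− cells, circles for replicate 1, triangles for replicate 2, black ticks for the mean of 2 arrays and a dotted line at the floor; stars mark members called when adjusted over the list alone. Red points lie to the right for the 17 starred cDC1 markers and to the left for the 12 starred cDC2 markers.

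Chemokine genes differed in both directions. Of 23 measured chemokines and receptors, 4 rose and 7 fell in CD8α+ cells when adjusted over the list alone, and 12 were not called. The chemokines Ccl3 (-3.40 ± 0.32, 10.5-fold), Ccl4 (-3.35 ± 0.31, 10.2-fold) and Ccl5 (-2.03 ± 0.30) and the CCR1 ligand Ccl9 (-3.50 ± 0.46) were lower in CD8α+ cells. The CXCR3 ligands Cxcl9 (4.20 ± 0.45, 18.4-fold) and Cxcl10 (1.17 ± 0.32), the CCR4 ligand Ccl22 (3.09 ± 0.42, 8.53-fold) and Xcr1 were higher. The lymph node homing receptor Ccr7 (-0.24 ± 0.38) was not called. As a set the list gave a camera adjusted p of 0.598 towards lower, while its median was 0.01. Without CD8α+ replicate 1 or without CD8α+ replicate 2, 3 members were higher and 3 lower, as on the deposited scale, and 7 were higher and 5 lower with median centring. Ccl5 is also an NK cell marker, and 9 of the 23 stand in another list.

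Of 18 measured cytokine genes, 7 fell in CD8α+ cells, 1 rose and 10 were not called when adjusted over the list alone, with a median of -1.10. Interferon gamma (Ifng, -3.64 ± 0.41, at least 4.45-fold, at the floor in 1 CD8α+ array), the interleukin-1 receptor antagonist Il1rn (-2.36 ± 0.34), oncostatin M (Osm, -2.00 ± 0.37) and lymphotoxin beta (Ltb, -2.11 ± 0.40, at least 2.10-fold) were lower. Il12b, which encodes the p40 subunit of interleukin-12, was the member that rose (2.02 ± 0.30, 4.05-fold). Il10 (-1.45 ± 0.70) and Il15 (0.72 ± 0.74) were not called. By camera the adjusted p was 0.00262, and adjusted p = 0.219 with an estimated correlation. It was 0.141 without CD8α− replicate 1, in a range of 0.000104 to 0.141 over the alternatives. Called members came to 0 higher and 1 lower without CD8α+ replicate 1, 0 without CD8α+ replicate 2, 4 higher and 10 lower without CD8α− replicate 1, 1 and 4 without CD8α− replicate 2, 1 and 1 on the deposited scale, and 1 and 2 with median centring. Ifng is made by NK cells as well, and 9 of 15 NK cell markers fell.

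Sensors of pathogens and nucleic acids differed in both directions, with 2 of 25 higher, 4 lower and 19 not called when adjusted over the list alone. Of these, the double-stranded RNA receptor Tlr3 (2.52 ± 0.34, 5.73-fold) and the profilin receptor Tlr12 (2.84 ± 0.41, at least 1.61-fold) rose in CD8α+ cells. The RNA sensors Ifih1 (-1.46 ± 0.32) and Tlr7 (-3.00 ± 0.70, at least 4.15-fold, at the floor in 1 CD8α+ array), the DNA-sensing adaptor Sting1 (-1.99 ± 0.45) and the lipoprotein receptor Tlr2 (-1.85 ± 0.43) fell. Unc93b1, the chaperone of the endosomal receptors (-0.03 ± 0.33), was not called. The sensors as a set gave a camera adjusted p of 0.0912, which was 0.0372 without CD8α− replicate 2 and 0.00955 at the stricter filter, in a range of 0.00955 to 0.205. Their median of -0.62 turned to 0.13 on the deposited scale and on median centring, and stayed negative relative to the shift of all genes. The 6 sensors called became 0 without CD8α+ replicate 1 or 2, and 4 higher and 9 lower without CD8α− replicate 1. On the deposited scale 1 was higher and 0 lower, and with median centring 3 and 1.

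Of 15 Fc and complement receptor genes, 6 fell and 0 rose in CD8α+ cells when adjusted over the list alone, with a median of -1.52. They were led by the shared Fc receptor chain Fcer1g (-2.93 ± 0.34, 7.61-fold), the paired receptors Pilrb1 (-2.39 ± 0.30) and Pilra (-1.71 ± 0.30) and the inhibitory receptor Cd300lf (-1.98 ± 0.31). Pilrb1 and Pilra are known as receptors of sialylated glycoproteins and Cd300lf as a receptor of phosphatidylserine. Of 18 C-type lectins, 7 fell, 1 rose and 10 were not called, with a median of -1.24. Cd209a, the mycobacterial glycolipid receptor Clec4e (-2.66 ± 0.38, 6.30-fold), Clec4d (-1.57 ± 0.36) and Clec4b1 (-2.50 ± 0.59, at least 2.41-fold, at the floor in 1 CD8α+ array) fell, and langerin (Cd207, 2.46 ± 0.61) rose. In the NADPH oxidase and phagosome list, the oxidase subunit Cybb (-2.73 ± 0.32, 6.65-fold) and Rab27a (-1.77 ± 0.32) fell, and 15 of 17 members were not called, Ncf4 (-0.05 ± 0.35) and Rac1 (-0.01 ± 0.31) among them. The camera adjusted p was 4.11e-06 for Fc and complement receptors, 0.000496 for lectins and 0.475 for the oxidase list. For the receptors and the lectins it was each time adjusted p = 0.219 with an estimated correlation. Without CD8α+ replicate 1 or 2 no member of the 3 lists was called. Leaving out CD8α− replicate 1 gave 5 oxidase members higher and 5 lower and 2 and 9 lectins, and leaving out CD8α− replicate 2 gave 10 receptors lower, 2 and 8 lectins, and 1 and 2 oxidase members. On the deposited scale no member of the 3 lists was lower, and 2 lectins were higher, while median centring gave 2 receptors, 3 lectins and 1 oxidase member lower, with 2 lectins and 1 oxidase member higher. A replicate block gave 2 lectins higher and 9 lower, and 1 oxidase member lower. Called markers of macrophages, monocytes and neutrophils fell as well, apart from Vcam1.

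Of 21 measured interferon-stimulated genes, 9 fell in CD8α+ cells, 1 rose and 11 were not called when adjusted over the list alone, with a median of -1.04. The antiviral genes Ifit1 (-2.52 ± 0.40), Oas2 (-1.85 ± 0.31), Ifitm3 (-1.57 ± 0.31) and Ifit3 (-1.76 ± 0.38) had the smallest p, and Cxcl10 was the member that rose. Mx1 (0.61 ± 0.30) and Stat2 (-0.06 ± 0.36) were not called. Against the other genes, camera gave an adjusted p of 3.78e-05, and adjusted p = 0.219 with an estimated correlation. On the deposited scale, without CD8α+ replicate 1 and without CD8α+ replicate 2 no member was called, and with median centring 2 were higher and 2 lower. A replicate block gave 0 higher and 7 lower. The NK, monocyte and macrophage lists had lower medians too, at -1.88, -1.05 and -0.69.

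Few antigen presentation genes were called. In the MHC class I list, Tapbpl, the TAP-binding protein-like peptide editor, rose (2.49 ± 0.32), and the other 19 of 20 members were not called, among them Tap1 (0.92 ± 0.40), Calr (1.41 ± 0.46) and H2-K1 (0.05 ± 0.32). This list had a camera adjusted p of 0.0374 towards higher with a median of 0.18. That p was 0.0526 with a replicate block, no longer under 0.05, and adjusted p = 0.309 with an estimated correlation. It was 0.0594 without CD8α+ replicate 1 and 0.366 without CD8α− replicate 1, in a range of 0.00231 to 0.366. Tapbpl alone made the count, which was 0 without CD8α+ replicate 1 or 2 and on the deposited scale, 2 without CD8α− replicate 1 or 2, and 7 with median centring, each higher. In the MHC class II list 0 of 21 members were called. H2-Ab1 (0.06 ± 0.30) and H2-Eb1 (0.10 ± 0.32) were not called. The invariant chain Cd74 gives no comparison here, since quantile normalization set it to the same value on all 4 arrays; its deposited signals were 10071 and 10677 in CD8α+ and 9452 and 9007 in CD8α− cells. The cathepsins Ctsl (-1.49 ± 0.36), Ctsd (-1.28 ± 0.39) and Ctsb (-1.08 ± 0.35) did not pass. For this list camera gave an adjusted p of 0.321 towards lower, against a median of 0.04. The sign of that median did not hold, at -0.33 without CD8α− replicate 1 and -0.34 without CD8α− replicate 2. Relative to the shift of all genes it was 0.06, and -0.27 on the deposited scale, -0.24 with trimmed mean scaling and -0.28 with median centring. Leaving out CD8α− replicate 1 called 5 class II members higher and 8 lower, and leaving out CD8α− replicate 2 called 2 lower.

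Among 19 costimulatory and coinhibitory genes, Tnfsf14 (LIGHT, -2.91 ± 0.53) and the inhibitory receptor Cd300a (-2.69 ± 0.52) fell in CD8α+ cells when adjusted over the list alone. Cd80 (0.32 ± 0.46), Cd86 (-0.05 ± 0.39) and Cd40 (-0.51 ± 0.34) were not called. The list had a median of -0.51, which was 0.10 on the deposited scale and 0.11 on median centring and below the shift of all genes on both. Its camera adjusted p was 0.0154, and adjusted p = 0.309 with an estimated correlation. It was 0.103 with trimmed mean scaling and 0.0573 with no filter, in a range of 0.0107 to 0.103. The 2 calls became 0 without CD8α+ replicate 1 or 2 and on the deposited scale, 2 higher and 7 lower without CD8α− replicate 1, and 1 higher and 1 lower with median centring. Of 36 transcription factors, Mycl (2.75 ± 0.41, at least 1.98-fold, at the floor in 1 CD8α− array) rose and Cebpb (-3.45 ± 0.39) fell. Mycl is known to sustain dendritic cell proliferation, and Cebpb to act in monocytes and macrophages. The camera adjusted p of the factors was 0.316, and 0.0372 without CD8α− replicate 2, in a range of 0.0372 to 0.897. No factor was called without CD8α+ replicate 1 or 2, 11 were higher and 9 lower without CD8α− replicate 1, 1 higher and 2 lower without CD8α− replicate 2, and 4 higher and 1 lower with median centring. Of 14 apoptotic cell uptake and scavenger receptors, Havcr1 (TIM-1, 2.09 ± 0.31, at least 2.78-fold) and the lipoprotein receptor Scarb1 (1.84 ± 0.33) rose, and Lrp1 (-2.12 ± 0.35) and the integrin Itgb3 (-1.78 ± 0.34) fell. As a set they gave a camera adjusted p of 0.911. None was called without CD8α+ replicate 1 or 2, 4 were higher and 4 lower without CD8α− replicate 1, and 4 and 3 without CD8α− replicate 2. On the deposited scale 3 were higher and 0 lower, and with median centring 5 and 1.

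Markers of other spleen cells were measured to describe what else the preparations may hold. Most NK cell markers fell in CD8α+ cells, with 9 of 15 members lower and 0 higher when adjusted over the list alone and a median of -1.88. The receptor Klra8 (-3.24 ± 0.48), Ccl5, the interleukin-2 receptor chain Il2rb (-2.60 ± 0.40) and the granule protein Nkg7 (-2.34 ± 0.39) were lower. The granzyme Gzma (-1.66 ± 0.90), the receptors Ncr1 (-1.46 ± 0.68) and Klre1 (-0.78 ± 0.67) and perforin (Prf1, 0.14 ± 0.49) were not called. Camera placed the list below the other genes with an adjusted p of 2.26e-06, and adjusted p = 0.219 with an estimated correlation. The count of lower members was 0 without CD8α+ replicate 1, 1 on the deposited scale and 5 with median centring, where 1 member was higher. T cell markers gave no call among 12 members, a median of 0.00 and a camera adjusted p of 0.892, with Cd3e at 0.44 ± 0.61. Without CD8α− replicate 2, 3 T cell markers were higher and 1 lower.

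Some macrophage, monocyte and neutrophil markers fell in CD8α+ cells as well. Of 9 macrophage markers, complement C1qb (-3.12 ± 0.39, at least 4.66-fold), Adgre1 (F4/80, -2.48 ± 0.32), Siglec1 (-2.23 ± 0.37, at least 1.56-fold, at the floor in 1 CD8α+ array) and Spic (-1.51 ± 0.38) fell when adjusted over the list alone, and the adhesion molecule Vcam1 rose (2.48 ± 0.56, 5.58-fold). Of 12 monocyte markers, Csf1r and Ms4a4c (-2.21 ± 0.40) fell, and Lyz2 (-0.84 ± 0.34) was not called. Of 12 neutrophil markers, the granule genes Camp (-2.29 ± 0.38), Lcn2 (-1.70 ± 0.37) and Ngp (-1.44 ± 0.32) fell, and S100a8 (-0.91 ± 0.33) was not called. The medians were -0.69, -1.05 and -1.11. The camera adjusted p was 0.00497, 6.85e-05 and 0.000128 in that order, and for each adjusted p = 0.219 with an estimated correlation. For macrophages it was 0.120 without CD8α− replicate 1 and 0.177 at the stricter filter, in a range of 0.000514 to 0.177. Without CD8α+ replicate 1 no member of the 3 lists was called, and without CD8α+ replicate 2 only 3 macrophage markers were lower. Leaving out CD8α− replicate 1 gave 6 monocyte markers lower, and 2 neutrophil markers higher and 6 lower, and leaving out CD8α− replicate 2 gave 6 macrophage, 4 monocyte and 10 neutrophil markers lower. On the deposited scale 1 macrophage marker was higher and 2 were lower, and no monocyte or neutrophil marker was called, while median centring left 1 monocyte and 0 neutrophil markers lower. A replicate block called 1 neutrophil marker lower, and trimmed mean scaling 9. Another list holds 1 of the NK, 1 of the macrophage, 5 of the monocyte and 1 of the neutrophil markers.

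Of 11 B cell markers, the kinase Blk (-1.90 ± 0.33) and Ighm (-1.38 ± 0.33) fell and Ms4a1 (CD20, 1.45 ± 0.31) rose when adjusted over the list alone. B cell markers had a camera adjusted p of 0.143, and 0.0397 on the deposited scale, 0.0479 with trimmed mean scaling and 0.0255 on median centring, in a range of 0.0255 to 0.382. No B cell marker was called without CD8α+ replicate 1 or 2 or on the deposited scale, and 2 were higher and 5 lower without CD8α− replicate 1 or without CD8α− replicate 2. With median centring 1 was higher and 0 lower, with trimmed mean scaling 1 and 6, with no filter 1 and 4, and with a replicate block 0 and 0. Among 12 plasmacytoid dendritic cell markers none was called, with Siglech at 0.66 ± 0.52 and a camera adjusted p of 0.282, and 2 were higher and 2 lower without CD8α− replicate 1. Their median of -0.48 was 0.23 on the deposited scale and 0.24 on median centring, below the shift of all genes on both. The 6 erythroid markers gave no call, a median of -1.08 and a camera adjusted p of 0.0963, which was 0.0340 on median centring, in a range of 0.0340 to 0.557. Of these, 1 was higher and 3 lower without CD8α− replicate 1, and 1 was lower without CD8α− replicate 2.

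**Figure D3:**
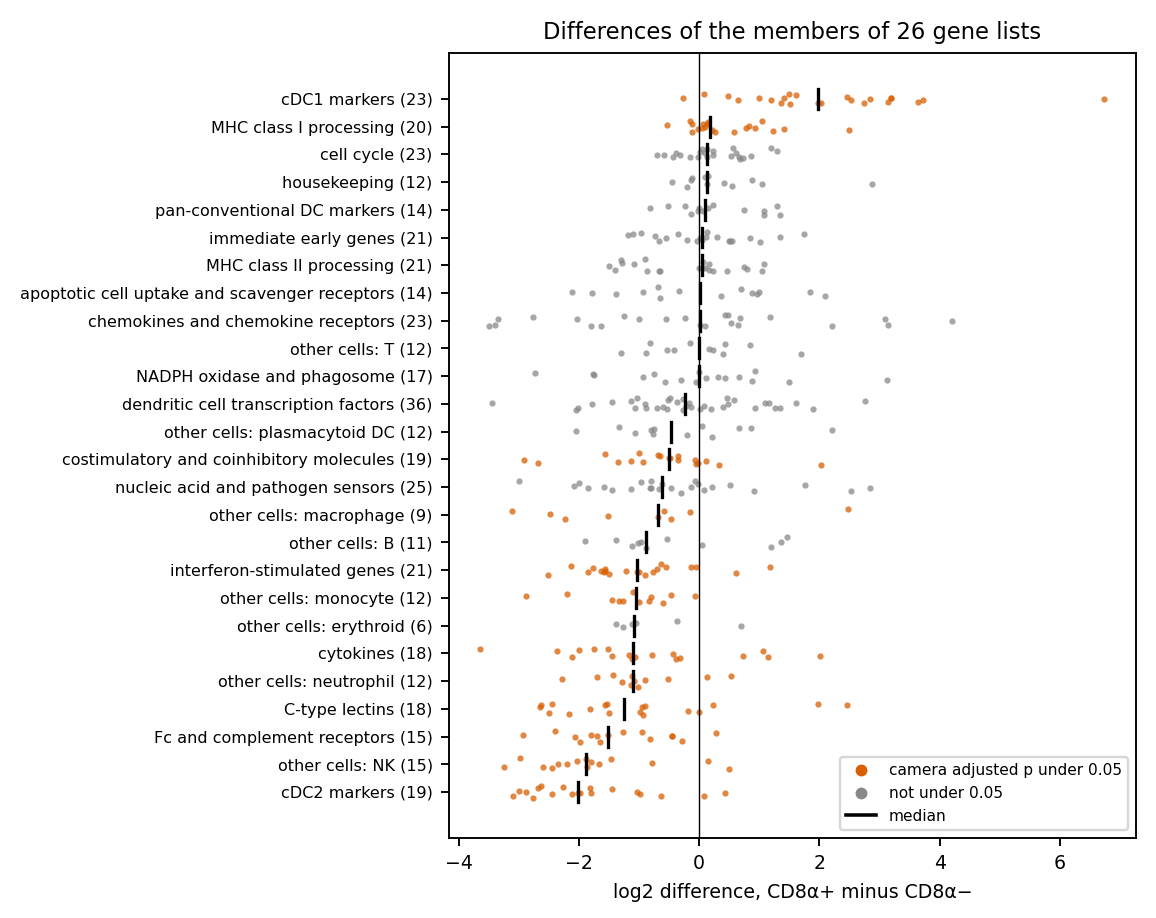
Each point is the log2 difference (x axis, CD8α+ minus CD8α−) of a measured member of a gene list (rows, number measured in brackets), with black bars at the list medians, shown with the arrays matched by quantile normalization. Orange marks the 12 lists with a camera adjusted p under 0.05, 2 higher and 10 lower in CD8α+ cells, none of which passed with an estimated correlation.

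Lists of pan-dendritic cell, cell cycle, immediate early and housekeeping genes gave few or no calls. With 2 arrays per group this does not show that their expression was equal. Of 14 pan-dendritic cell markers 0 were called, including Flt3 (1.08 ± 0.47), Zbtb46 (1.35 ± 0.75) and Itgax (CD11c, -0.81 ± 0.38), with a camera adjusted p of 0.411. Of 23 cell cycle genes 0 were called, with Mki67 at 0.13 ± 0.34 and Mcm2 at 1.30 ± 0.32, and the camera adjusted p was 0.222. Of 21 immediate early and heat shock genes 0 were called, with Fos at 0.84 ± 0.68, Egr1 at 0.01 ± 0.42 and Hspa1a at 1.75 ± 0.47, and the camera adjusted p was 0.892. Of 12 housekeeping genes, the lysosomal enzyme Gusb rose (2.87 ± 0.33, 7.33-fold) and Actb (0.42 ± 0.34) was not called. The camera adjusted p of the housekeeping list was 0.198. Leaving out CD8α− replicate 1 called 5 pan-dendritic markers higher and 1 lower, 5 immediate early genes higher and 5 lower, and 3 housekeeping genes higher. Leaving out CD8α− replicate 2 called 1 immediate early gene higher, and without CD8α+ replicate 1 or 2 no housekeeping gene was called. With median centring 2 immediate early and 2 housekeeping genes were higher.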

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

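Trimmed mean scaling and array weights were added after seeing the data, when the deposited scale, the plan's main one, also became an alternative. The other alternatives were planned. Against 0 probe sets and 0 genes called by limma, median centring called 406 and 195 (362 and 173 brighter in CD8α+ cells), the filter at the 75th percentile 37 and 22, the intensity trend 60 and 37, and the robust trend 51 and 30. Leaving out 1 array gave 0 to 2868 probe sets and 0 to 1256 genes, the highest without CD8α− replicate 1. Apart from a replicate block, the remaining alternatives, a fold of at least 2 and averaged probe sets included, called 0. The replicate differences of the groups correlated at 0.0311. This cannot decide whether replicate numbers pair the arrays, since probe sets of a gene hardly shared the CD8α− difference (r = 0.0216). A replicate block called 16 probe sets and 10 genes and moved the MHC class I list to a camera adjusted p of 0.0526. Probe sets at unadjusted p under 0.05 (3501) came to 6873 with median centring, 6555 with no filter, 2195 at the 75th percentile and 1121 to 9728 with 1 array left out. Lists passing camera numbered 9 to 14 over these alternatives and 0 with an estimated correlation. cDC1 members called (17) came to 8 with no filter and 5 to 20 with 1 array left out, and cDC2 members (12) to 0 on the deposited scale and 1 to 14 with 1 array left out. Of the 112 memberships, Zeb2 alone changed sign, to 1.20 on the deposited scale and 0.29 with the floor at the 40th percentile, where another of its probe sets represents it. Without CD8α+ replicate 1, 99 were no longer called and without CD8α+ replicate 2, 86, since the spread then rests on the CD8α− pair; on the deposited scale 73 were not called, with median centring 40, with no filter 38, with array weights 32 and with a replicate block 15. The causes of the other moves were not tested. The lone array of a group is assumed to vary like the other group. Without CD8α− replicate 1 the spread is therefore that of the CD8α+ pair, and CD8α− replicate 2, the dimmest array, stands alone. Array weights were 2.91 for each CD8α+ and 0.344 for each CD8α− array. Signals within the range of the Bacillus controls limit folds to lower bounds.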

Other observations

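The tests of 5′ signal loss and of natural killer (NK) cell markers were chosen after the values were seen; those of dim-signal noise and of paired probe sets were planned before them. Beyond the fixed lists, further genes are named here after their values were seen. Lower in CD8α+ cells stood the apolipoprotein Apoc2 (-4.00 ± 0.38), the phospholipid transfer protein Pltp (-3.53 ± 0.36) and the stress-induced mTOR inhibitor Ddit4 (-3.02 ± 0.34). Standing higher in CD8α+ cells were the adhesion-like gene Hepacam2 (3.63 ± 0.32), the guanine nucleotide exchange factor Fgd6 (3.22 ± 0.31), the semaphorin Sema4a (2.82 ± 0.32) and the metalloprotease Adam19 (2.64 ± 0.32). None had an adjusted p under 0.05 over all genes in the main limma fit, on quantile-normalized values (each 0.116). On the deposited scale, the plan's main one, the lowest limma adjusted p of any probe set was 0.207. Each was among the 37 genes called with an intensity trend, at adjusted p from 0.0458 to 0.0491. No theme was tested for these genes.

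Other splits of the 4 arrays gave fewer differences, but each puts an array of each population in both groups. Any difference between the populations then widens the spread, so their lower counts add no support to the real split. The real split had 3501 probe sets at unadjusted p under 0.05, and the highest of the other 2 splits had 299, with 0 adjusted calls in each. With 3 splits no share under 0.05 can be reached.

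The CD8α− arrays differed from each other more than the CD8α+ arrays did. Noise of dim signals as the whole cause would bring both pairs together among bright probe sets; the median replicate difference fell from 0.988 in the dimmest to 0.609 in the brightest 25% for CD8α− cells and from 0.548 to 0.108 for CD8α+ cells, so their ratio was 1.80 and 5.66 (95% bootstrap interval of the latter 5.41 to 5.90). A difference in cell content or RNA abundance between the CD8α− preparations would move both probe sets of a gene together, but their replicate differences correlated at 0.0216. The difference between the groups gave 0.686 on replicate 1 and 0.262 on replicate 2, which holds the dim array, and the CD8α+ pair gave 0.0599. This argues against such a difference as the whole cause, while a smaller part is not excluded. Loss of 5′ signal from every transcript on replicate 2 would raise both control ratios, but that of Actb was 0.759, below the other arrays, while that of Gapdh was 10.7. What also stays open is a candidate explanation that the data cannot test further, a probe set-specific difference in amplification or labelling between these arrays. Whether they followed different protocols is not given in the sources used here.

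The NK list stood lower in CD8α+ than in CD8α− cells. The dim CD8α− replicate 2 is not its source, since against CD8α− replicate 1 alone the list's median was -2.14 (95% bootstrap interval -2.66 to -1.65) and 13 of 15 members were lower. A lower share of dendritic cells in the CD8α− preparation, raising all other cell types alike, is argued against as the whole cause, since these types moved apart. Among markers above the highest Bacillus control, a bound chosen after the values were seen, the NK median was -1.88 (95% bootstrap interval -2.45 to -1.56) and that of T cells 0.16 (-0.81 to 0.44). The 7 lists differed (Kruskal-Wallis permutation p = 0.00190, and 0.0125 to 0.0147 with the other scalings). NK minus T was -2.03 (permutation p = 0.00100), and -1.62 to -1.71 with the other scalings (p at most 0.00900). With markers above 2 times the control it was -1.87 (permutation p = 0.0238, and at most 0.0345 over the scalings). Above 3 times, with 10 and 5 markers left, it was -1.54 (permutation p = 0.155) and -1.38 with the other scalings (p at most 0.168), no longer under 0.05. NK and T cells had the lowest and highest of the 7 medians, and the permutation p-values of this pair do not allow for its choice. A smaller shared part stays open: the medians of macrophages (-1.51), monocytes (-1.05), neutrophils (-1.11), erythroid cells (-1.08) and B cells (-0.93) were below 0 too. Without NK cells the 6 lists did not pass (0.0556, and 0.227 to 0.233), and relative to all genes the full T list stood at 0.02, and at -0.26 to -0.30 with the other scalings. NK cells in the CD8α− preparation may remain a source: the median of Prf1, Klre1, Ncr1 and Gzma was -1.12, but Prf1 and Klre1 did not separate the groups, so this cannot be told apart from expression of such genes by CD8α− dendritic cells, the biological difference the design names, which was not tested. Mean log2 signals in CD8α− cells were 11.15 for Ccl5, 10.42 for Klrd1 and 9.35 for Gzma, which cannot be ranked between probe sets and decide nothing here, and no sort that would remove NK cells is given in the sources used here.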
